A study of Glycine max with 4 samples.

How the data were processed

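RNA-seq libraries were made from total RNA of young shoot tips and vegetative buds of 2 soybean isolines, Clark standard and Clark five-foliate, per the labels' protocols, and sequenced on an Illumina Genome Analyzer. Each combination of genotype and tissue had 1 library. The protocol speaks of several plants per harvest, but the 4 libraries carry no replicate within a group. The titles number the shoot tip libraries 1 and the bud libraries 2, so this number is the tissue.

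The authors deposited RPKM values, a read number scaled by model length and library total, in 2 tables, 1 for each tissue. Bowtie is named in the submitters' processing notes without a version, and the genome build, annotation release and treatment of reads with several matches are not given in the sources used here. Both tables list the same 78773 models, with alternative models of a gene in separate rows. The bud table also held 708957 rows with no identifier or value and 7 empty columns, which were dropped. No gene name stands beside an identifier, and 0 identifiers matched the reference table of 59048 genes (assembly Glycine_max_v4.0), so genes were not named. The chromosome and order number of a gene were read from its identifier, and no coordinates were used.

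Whole reads behind the RPKM values were recovered by searching for a whole model length from 20 to 20000 and whole library totals that turned all values of a model into whole numbers within 0.0005 reads. Of 62593 models with 4 values above 0, 99.9904% came out whole at a common length, against 0% of 3000 models whose values had been shifted at random. In simulated data with known totals, all reads were recovered for 96.2% of 2000 models. Where several lengths fitted, the fewest reads were taken. The totals count alignments, and a read can count for several models. Recovered reads of all models summed to 96.28% to 98.09% of the totals. In a model of 1 kb, 3 reads corresponded to 0.0196 RPKM in the standard shoot tip, 0.0215 in the five-foliate shoot tip, 0.0308 in the standard bud and 0.0290 in the five-foliate bud. The reported counts of genes used the deposited RPKM. Recovered reads or lengths entered the intervals, the floors, the draws of counting error, the check for identical reads, the length trend and the voom weights.

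The model with the highest mean RPKM stood for each gene. Ratios were log2((five-foliate RPKM + 1)/(standard RPKM + 1)), a scale that understates changes of low genes, for genes with at least 1 RPKM in at least 1 library of the tissue. Within a tissue genes were counted at a 2-fold difference with no test. Fold intervals are 95% exact binomial intervals of the recovered reads. Where a library had no read, the fold is given with 3 reads in place of 0, beside the lower limit of the interval. The intervals compare libraries, not genotypes, and cover counting error only. Overlap between tissues was set beside the product of the list sizes divided by the number of genes, and beside 1000 draws matched in 20 bins of mean expression. The tissues share no library.

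Genotype over both tissues was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2(RPKM + 1), terms genotype and tissue, Benjamini-Hochberg threshold 0.05), which left 1 residual degree of freedom. Tested on simulated data over 34418 genes with 200 changed and an assumed dispersion of 0.02, it found 89% of 2-fold changes with 14 false calls, 100% of 4-fold changes with 27 and 100% of 8-fold changes with 21. In each of these runs the false calls were a larger share of all calls than the threshold of 0.05 allows on average. With 0 genes changed it made 0 calls. The smallest absolute log2 ratio called in the deposited data was 1.40, so the shares of changes found do not describe the power of the fit on the real data. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Gene order was examined in windows of 50 consecutive genes that passed the filter in both tissues, against 10000 shuffles of genes over places.

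The comparisons, the alternatives and the rule for named genes were fixed before the data were examined. The windows departed from the plan, which had consecutive gene models in place of genes passing the filter. The rule took the 12 genes with the highest and the 12 with the lowest ratio in each tissue at 5 RPKM or more in the higher library, and the 10 per direction with the largest smaller ratio over both tissues. Only 2 identifiers per direction are printed, the first 2 of the list over both tissues, because names were missing. The 31 gene lists fixed in advance select genes by name and could not be applied. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 RPKM, centred ratios, upper-quartile scaling, a 3-fold threshold, other priors in limma and windows of 25 and 100 genes. Groups of 1 library allowed no outlier test and no omission of replicates.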

Results

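RNA was sequenced from 2 soybean isolines, Clark standard and the leaf mutant Clark five-foliate, in 2 tissues. Isolines are lines bred to share most of their genome and to differ at a trait. Standard soybean leaves are trifoliate, and the five-foliate line is named for its extra leaflets. Young shoot tips and vegetative buds came from multiple 4-week-old greenhouse plants, and each of the 4 combinations of genotype and tissue was represented by 1 library. No comparison within a tissue therefore had a replicate check, and no p-value was computed for it. The deposited values were RPKM for 78773 gene models of 69145 genes. The totals behind them, recovered from the values, were 152791817 alignments for the standard shoot tip, 139769051 for the five-foliate shoot tip, 97532923 for the standard bud and 103618555 for the five-foliate bud. Intervals and floors below cover counting error only. The files give gene identifiers without names, so genes are described by identifier, chromosome and level, with at most 2 identifiers for each direction.

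The first comparison asked how the genotypes differed in the shoot tip. Glyma04g35130 on chromosome 4 had 480.4 RPKM in the standard shoot tip and 0.181 RPKM in the five-foliate shoot tip, a level 2654-fold higher in the standard line (95% exact binomial interval 2008 to 3588, from 142173 and 49 reads). The gene with the next lowest ratio, on chromosome 15, had 1484 RPKM in the standard and 8.27 RPKM in the five-foliate library. In the other direction, Glyma13g25800 on chromosome 13 had no read in the standard library and 15.2 RPKM in the five-foliate library. With 3 reads in place of 0 the five-foliate level was 769.6-fold higher, and the exact binomial interval began at 625-fold. Glyma02g09290 on chromosome 2 had 1.09 RPKM in the standard and 24.0 RPKM in the five-foliate library, 22.0-fold higher (interval 19.3 to 25.3). Of 36537 genes with at least 1 RPKM in either library, 4497 differed at least 2-fold on the log2(RPKM + 1) scale.

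How the list divided between directions depended on the settings: 2780 genes were higher and 1717 lower in the five-foliate shoot tip as deposited, 1082 higher and 3053 lower with ratios centred on their median, and 1354 higher and 2638 lower with upper-quartile scaling. Centring moves all ratios alike, so other genes passed the threshold and no gene past it in one direction passed it in the other. The median log2 ratio of all genes passing the filter was 0.34 as deposited and -0.01 after centring. The count itself was 7759 with a pseudocount of 0.1, 1544 with a pseudocount of 5 (819 higher and 725 lower) and 1210 with a 3-fold threshold (574 higher and 636 lower). The 20 most abundant genes of the standard shoot tip held 14.9% of its RPKM sum, and 15 of them were at least 2-fold lower in the five-foliate shoot tip, where the same genes held 4.26%. They held 1.27% in the standard bud and 1.17% in the five-foliate bud. Choosing genes by their level in the standard shoot tip favours lower levels and shares in every other library.

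**Figure D1:**
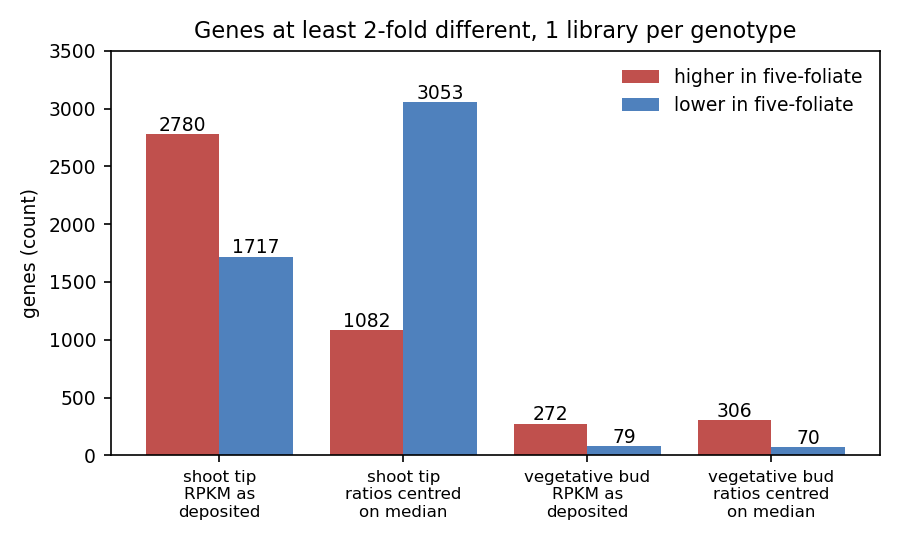
Bars give the number of genes at least 2-fold higher or lower in the five-foliate line, for each tissue, with RPKM as deposited and with log2 ratios centred on their median. In the shoot tip the longer list is that of higher genes as deposited (2780) and that of lower genes after centring (3053), while in the bud most genes are higher under both scalings.

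The same question was asked of the vegetative bud. Glyma04g35130 was again the gene with the lowest ratio, with 166 RPKM in the standard bud and 0.135 RPKM in the five-foliate bud, 1235-fold higher in the standard line (interval 849 to 1874). Glyma04g35120, its neighbour by identifier on chromosome 4, had 15.9 RPKM in the standard bud and no read in the five-foliate bud. Its five-foliate level was 35.1-fold lower with 3 reads in place of 0, and the exact binomial interval began at 27.98-fold. Glyma13g25800 had 1 read in the standard bud, or 0.0103 RPKM, against 12.9 RPKM in the five-foliate bud, a ratio of 1253 (interval 224 to 49521). Glyma02g09290 had 3.22 RPKM and 36.1 RPKM, 11.2-fold higher in the five-foliate bud (interval 10.1 to 12.4). Of 38332 genes passing the filter, 351 differed at least 2-fold, 272 higher and 79 lower in the five-foliate bud.

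Most of the bud genes were also higher in the five-foliate line after centring, with 306 higher and 70 lower. The count was 623 with a pseudocount of 0.1, 77 with a pseudocount of 5, 163 with a filter of 5 RPKM and 129 with a 3-fold threshold. Counting error alone gave at most 1 such gene in the shoot tip and at most 2 in the bud over 20 simulated draws. The log2 levels of the bud libraries had a Pearson correlation of 0.986 across 40448 genes, against 0.912 for the shoot tip libraries, and genes are not independent replicates. Whether the genotype difference was larger in the shoot tip than in the bud was not tested, because each value rests on 1 library.

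**Figure D2:**
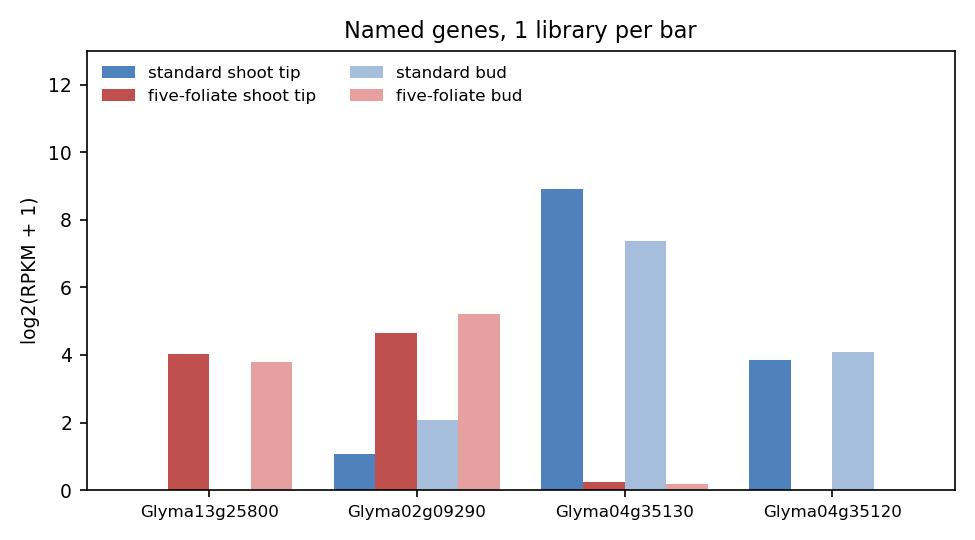
Bars give log2(RPKM + 1) of the 4 identified genes in each of the 4 libraries, and an absent bar is a value near 0. Glyma13g25800 and Glyma02g09290 are higher in both five-foliate libraries, and Glyma04g35130 and Glyma04g35120 are near 0 in both.

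The next comparison asked which genes differed between genotypes in the same direction in both tissues. The 4 identified genes were chosen from this list, so their common direction follows from the choice. Glyma04g35130 and Glyma04g35120 were lower in both five-foliate libraries, and Glyma04g35120 had 13.4 RPKM in the standard shoot tip and no read in the five-foliate shoot tip, at least 39.9-fold lower. Glyma13g25800 and Glyma02g09290 were higher in both five-foliate libraries, by the folds given above. Of 34421 genes passing the filter in both tissues, 89 were at least 2-fold different in the same direction, 51 higher and 38 lower in the five-foliate line.

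The 38 genes lower in both were 77.6% of the 49 genes lower in the bud among these 34421, where independent lists would share 1.80 and lists matched on mean expression shared at most 7 in 1000 draws. The 51 genes higher in both were 24.5% of the 208 higher in the bud, against 16.4 for independent lists and at most 30 in the matched draws. A further 50 genes, 24% of these 208, were lower in the five-foliate shoot tip and higher in the five-foliate bud. Independent lists would share 7.63 and the matched draws shared at most 17. The opposite combination was shown by 0 genes, against 3.87 for independent lists and a median of 3 in the matched draws. These expectations treat each gene as separate, so copies that share reads would count more than once. Among the 89, 2 had reads identical to another gene in all 4 libraries. A second check covered only 23 genes, at 1 RPKM or more in one line and 0.1 or less in the other, in both tissues. Of these, 4 had a standard bud RPKM identical to that of another, and these 4 were among the genes lower in both. The other genes lower in both were not checked in this way. Across all 34421 genes, the log2 ratios of the tissues had a Pearson correlation of -0.0278 (95% bootstrap interval over genes -0.0615 to 0.0132) and a Spearman correlation of -0.0677, and genes are not independent replicates. With a filter of 5 RPKM the Pearson correlation was 0.0330, and without the 1% of genes with the largest ratios it was -0.0697. The number of shared genes was 16 with a pseudocount of 5, 36 with a filter of 5 RPKM, 32 with a 3-fold threshold and 137 with a pseudocount of 0.1.

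**Figure D3:**
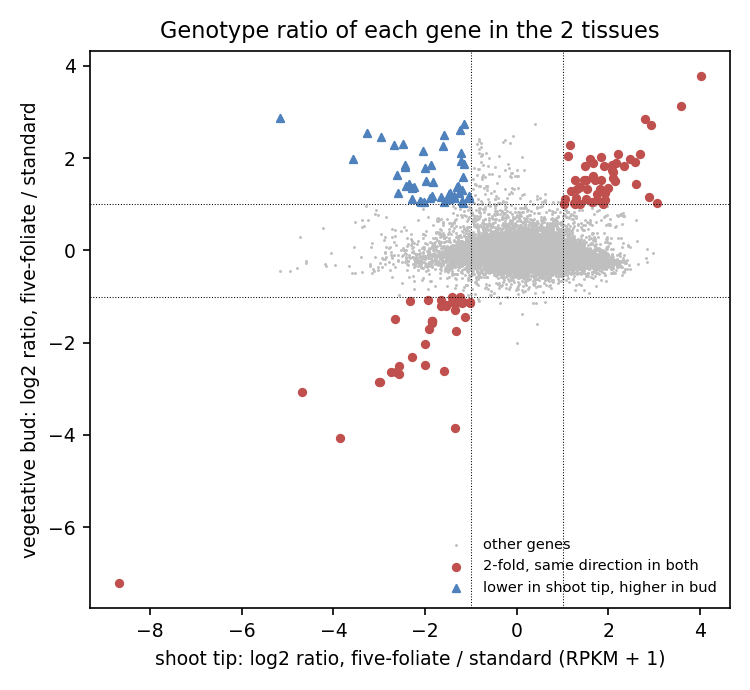
Each point is 1 of 34421 genes, with its log2 ratio of five-foliate to standard (RPKM + 1) in the shoot tip on the horizontal axis and in the vegetative bud on the vertical axis. Circles mark the 89 genes at least 2-fold different in the same direction in both tissues and triangles the 50 genes lower in the shoot tip and higher in the bud.

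**Figure D4:**
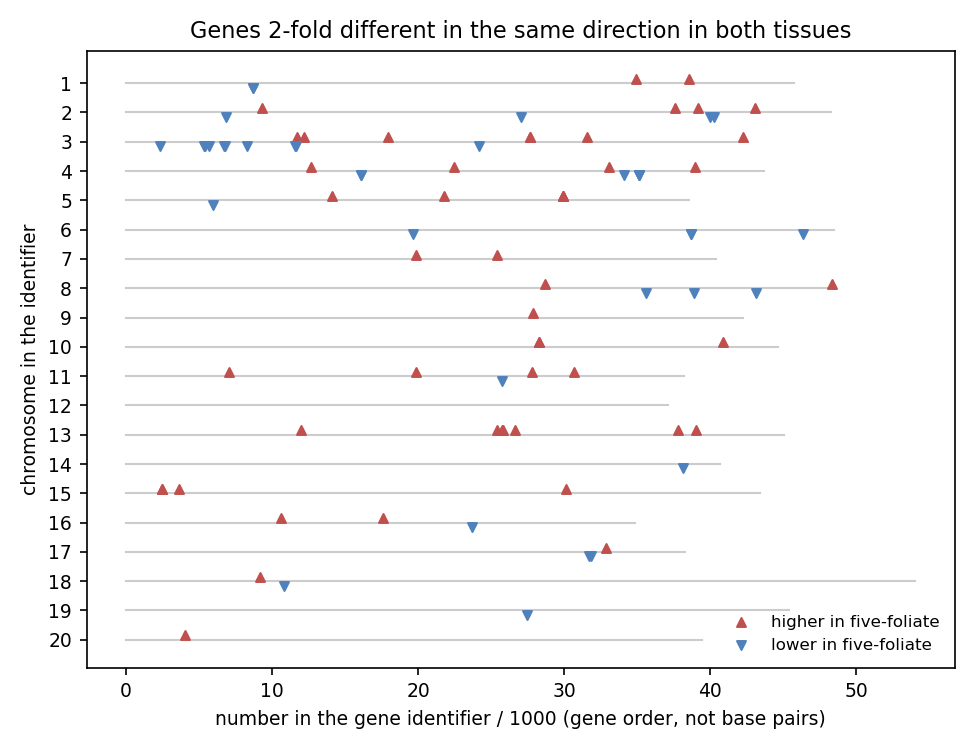
Triangles mark the genes at least 2-fold different in the same direction in both tissues that have a chromosome in their identifier, by chromosome (vertical axis) and number in the identifier divided by 1000 (horizontal axis, gene order and not base pairs). Upward triangles are higher and downward triangles lower in the five-foliate line, and chromosome 3 holds 17 of the 87.

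A limma model with genotype and tissue as terms called 141 genes at a Benjamini-Hochberg adjusted p under 0.05, 61 higher and 80 lower in the five-foliate line. It called 47 with a filter of 5 RPKM, where fewer genes were tested, and 245 with a pseudocount of 5. Glyma04g35130 had a fitted log2 ratio of -7.94 (adjusted p = 1.449e-93 in limma) and Glyma04g35120 of -3.96 (adjusted p = 1.231e-21 in limma). Glyma13g25800 had a fitted log2 ratio of 3.90 (adjusted p = 4.935e-21 in limma) and Glyma02g09290 of 3.36 (adjusted p = 3.313e-15 in limma). These genes were chosen for a common direction in the 2 tissues. Of the 141 genes, 63 were at least 2-fold different in the same direction in both. A further 77 of the 141 were under 2-fold in the bud. Of the 61 higher genes, 18 lay in a single run of 50 genes on chromosome 13, and 1 of these 18 was at least 2-fold higher in both tissues. That run was picked for the largest share of the five-foliate bud RPKM sum, which favours genes higher in that line. The fit had 1 residual degree of freedom, its spread was that between tissues and not between plants, and it gave every gene the same standard error of 0.376, so the calls amounted to a threshold on the mean ratio. The limma calls ended, with 0 genes, when ratios were centred on their median (398 at an unadjusted p under 0.05), when no filter was used (1903) and when tissue was left out (109). The prior degrees of freedom are the weight that limma gives to a spread shared by all genes. They were infinite in the reported fit and 2.6, 0.536 and 3.96 in these settings, so the calls rested on the shared spread.

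The last comparison set the tissues side by side within each genotype. In both genotypes 4895 genes differed at least 2-fold between bud and shoot tip with the same sign, 3036 higher and 1859 lower in the bud, among 40448 genes with at least 1 RPKM in any library. The standard line alone had 11683 such genes and the five-foliate line 7003. With a pseudocount of 0.1 the count for both genotypes was 8028, 5242 higher and 2786 lower in the bud. Genes at 5 RPKM or more in both libraries of a tissue and at 0.1 RPKM or less in both of the other numbered 31 for the bud and 3 for the shoot tip. In the standard line 8144 of the 11683 genes were higher in the bud as deposited, and 4910 of 9823 with upper-quartile scaling. The tissues stand in separate tables, which used the same formula, and the tissue difference was not tested.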

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

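The centred counts were planned before the data were examined, the removal of the length trend was chosen before its result was seen, and the other tests in this part were chosen after their results or related values had been seen.

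A group of 50 genes was at least 2-fold lower in the five-foliate shoot tip and at least 2-fold higher in the five-foliate bud, so the difference between the libraries of the 2 genotypes had opposite signs in the tissues. With 1 library per group the difference was not tested against plants. Median levels of these genes were 6.16 RPKM in the standard shoot tip, 0.733 RPKM in the five-foliate shoot tip, 1.19 RPKM in the standard bud and 4.87 RPKM in the five-foliate bud.

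An exchange of genotype labels in 1 tissue is argued against by genes on in one genotype (1 RPKM or more) and off in the other (0.1 RPKM or less), of which 23 followed the labels in both tissues and 2 followed the crossed pattern. The median of the 50 genes for the log2 ratio of five-foliate shoot tip to mean bud was -0.83 (matched random lists -0.24 to 0.08), but choosing genes low in that shoot tip and high in the five-foliate bud sets a low ratio, so a bud difference along the shoot tip to bud axis stays open. A genotype effect that differs between tissues stays open too, as does a difference in the state of the plants at harvest, and neither was tested.

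The count of 2-fold genes was several times larger in the shoot tip (4497) than in the bud (351). A few abundant genes taking most of the reads, counting error and model length are argued against as the whole cause: the count was 4135 after centring (bud 376), counting error gave at most 1, and it was 4085 with the trend over 50 length bins removed (bud 377). The standard shoot tip may instead have been sampled farther from the bud in development: across genes its levels correlated at 0.755 with the standard bud, against 0.857 for the five-foliate shoot tip. The test across genes gave a Pearson correlation of 0.0134 and a Spearman correlation of -0.0447. Both sides of the test share the five-foliate shoot tip library, so it cannot decide. With 1 library per genotype in the tissue, sampling farther from the bud and a genotype effect cannot be told apart. In the five-foliate shoot tip, 23.2% of the 1717 genes lower there and 21.3% of the 2780 higher there were at least 2-fold above the bud mean (7.07% of all genes), and 10.9% and 11.7% were at least 2-fold below it (9.67% of all genes), which does not set the directions apart.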

How the results depend on the processing

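With a pseudocount of 0.1 the counts rose to 7759 (shoot tip), 623 (bud), 137 (both tissues) and 8028 (between tissues), and with a pseudocount of 5 they were 1544, 77 and 16, while limma called 245. A filter of 5 RPKM gave 163 in the bud, 36 in both tissues and 47 in limma, where fewer genes were tested. The 3-fold threshold gave 1210, 129 and 32. The limma fit called 0 genes with no filter, 0 with no replicate block (tissue left out) and 0 with centred ratios. Its prior degrees of freedom were 0.536, 3.96 and 2.6 in these settings, in that order. Their median over genes was infinite in every setting that called genes, and why they changed was not tested. The Pearson correlation between tissues was 0.0330 with a filter of 5 RPKM, the opposite sign, and -0.0697 without the 1% of genes with the largest ratios, and the cause was not tested. The other 22 values of these results stayed within 1.5 times the reported count, inside the interval or on the same side of 0.05. Among them, the counts of 2-fold genotype differences with no filter could not have changed. With a pseudocount of 1, a gene under 1 RPKM in both libraries cannot reach a 2-fold ratio. For single genes, 31 of the values of the log2 ratio moved beyond their counting interval and 9 did not, with no change of sign. Glyma13g25800 in the shoot tip went from 4.01 to 7.25 with a pseudocount of 0.1 and to 2.01 with a pseudocount of 5, and in the bud from 3.78 to 6.88 and 1.84. In the shoot tip, centring and upper-quartile scaling changed which genes passed the threshold, and so the split of higher and lower genes, while the count stayed within 1.5 times.

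Chosen after the data were seen were voom weights in limma (144 genes, 95 of them among the 141), genes with identical reads counted once and 1 gene kept of each run of neighbours. A count model on the recovered reads was planned and not run, because the deposited unit is RPKM, and the alternatives for gene lists were not run. No paired analysis was possible within a tissue because each group has 1 library. Dropping the standard shoot tip library would leave no shoot tip comparison.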

Other observations

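All tests in this part except the window shuffle and its planned widths and threshold were chosen after the results were seen. The plan had windows of consecutive gene models, and consecutive genes that passed the filter in both tissues were used instead.

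Genes different in both tissues lay close together in gene order. Of 34272 ordered genes 87 were different, and the richest window of 50 genes held 5 (permutation p = 0.0007 over gene places, shuffled median 2). Reads shared between neighbouring copies no more than 3 places apart are argued against as the whole cause. With 1 gene kept of each run of such neighbours, the permutation p over gene places was 0.011. Copies farther apart in a window were all kept, so reads shared between them stay open as a cause. A segment that differs between the isolines stays open. With every gene counted, windows of 3 or more genes also lay on chromosomes 4, 5, 13 and 17. With 1 gene kept of each run, which merges close genes of the same direction, 2 separate windows held 3 or more genes, both on chromosome 3. The shuffles had a median of 0 and at most 4 (permutation p = 0.036). Rich windows are the pattern itself and do not favour a segment over another cause of clustering. The 2 windows on chromosome 3 span identifier numbers 5320 to 6720 and 8310 to 12150, and sequence differences between the lines were not examined here.

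Chromosome 3 held 17 of its 1584 ordered genes different in both tissues, 7 higher and 10 lower in the five-foliate line, or 10.7 per 1000. The highest density of any chromosome had a median of 4.93 per 1000 in the shuffles (permutation p = 0.0001, the smallest that 10000 shuffles can give). With 1 gene kept of each run, chromosome 3 held 14 and the permutation p was 0.0001. Chromosome 12 held 0 of 1445.

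In both tissues 16 genes were on in the standard line and off in the five-foliate line, and 7 were on in the five-foliate line and off in the standard. 4 of these 23 had a standard bud RPKM identical to that of another, as copies that share reads would. A run of 50 genes on chromosome 13, identifier numbers 11810 to 13300, held 16.9% of the RPKM sum of the five-foliate bud, 10.6% of the standard bud, 9.50% of the five-foliate shoot tip and 2.54% of the standard shoot tip. It was picked as the run of 50 genes with the largest share of the five-foliate bud, so a high share there is favoured by the choice.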
